A study of Mus musculus with 6 samples.

How the data were processed

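RNA was extracted from mouse hearts with Trizol, and libraries were made with an Illumina TruSeq RNA kit from total RNA, per the labels' protocols. The deposited table holds FPKM values (fragments per kilobase of transcript, scaled to mapped library size), per the file headers, with 1 column per library. The authors used Cufflinks and the mouse genome build mm10, per the submitters' processing notes. Its version, the aligner, the annotation and any filter are not given in the sources used here. The column layout is that of a Cufflinks gene table. No further normalization of the deposited FPKM is recorded, and totals per library ran from 696803 to 867428.

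The table lists 23995 genes by symbol. In addition, 1 line held no value and is not reported here. Of the symbols, 27 had been turned into calendar dates, as spreadsheet programs do, and these genes were kept under their position and never named. Mitochondrially encoded genes are not listed (0 genes). Start positions were raised by 1 to count from 1, since 10291 starts then equalled an annotated exon start, against 942 as printed. Of the symbols, 22669 were found in GENCODE M21, which uses the same build, and strand, gene type and exon counts were taken from it. The kit was not stated to keep strand, so reads of overlapping genes on opposite strands cannot be told apart.

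Each library was mapped to its column by the short name in its description. The groups were wild type and cardiomyocyte-specific, inducible *Ltbp4* knockout, both after TAC, with 3 libraries each. FPKM values are not counts, so no count model was used. Depth was recovered from low values. For genes with a single annotated transcript over 1000 bases, FPKM times effective length in kilobases is a whole multiple of what 1 fragment is worth. Between 76.8% and 83.8% of such low values fell within 0.15 of a whole number, and the depths given in the report are approximate. The interval given for *Ltbp4* comes from the spread between the 4 samples in the limma fit, moderated by the spread of other genes. The median prior degrees of freedom were 4.55, beside 2 residual ones.

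All 15 pairs of libraries were compared on the recovered reads of these genes, in 5 depth bins from 10 to over 1000 reads. The index was the median squared deviation over that of binomial counting. Wild-type libraries 1 and 3 (Pearson's r across genes 0.992) and knockout libraries 2 and 3 (0.993) stayed under 3 in every bin, while the other 13 pairs had r from 0.894 to 0.944. Genes are not independent replicates, so these r values only describe the libraries. Each of the 2 close pairs was averaged as FPKM and counted as 1 sample. This was decided after the libraries had been compared. The fit fixed before the data were examined took the 6 libraries as separate samples with a term for the record set (the 2 runs of record numbers), and its gene and list counts, its *Ltbp4* value and the lists that it did not call are given as an alternative. In the 4 samples that term could not be estimated.

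Genes with FPKM of at least 1 in at least 3 libraries were tested (12485 genes) on log2(FPKM + 1), with a pseudocount of 1 and no further scaling. A fold change on this scale understates the change of low genes. The test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend and robust), with moderated tests for either direction, Benjamini-Hochberg adjustment and a threshold of 0.05. The fit of the 4 samples had 2 residual degrees of freedom. Of 30 gene lists fixed before the data were examined, the 24 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01. The lists of neutrophil, lymphocyte, mesothelial, skeletal muscle and mitochondrially encoded genes had too few, and the sex-linked list was reported as values only. An estimated correlation and limma's fry were the alternatives. Fry tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. The exact permutation test of *Ltbp4* used scipy 1.17.1 on log2 values.

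The genes named were chosen by a rule fixed before the data were examined. It took *Ltbp4*, the 12 genes with the largest rise and the 12 with the largest fall among those that passed and did not overlap (filled up by the smallest p where fewer passed), up to 4 members of each tested list by smallest p, a fixed set of inflammasome, hypertrophy, collagen and TGF-beta genes, and the sex-linked genes. Symbols that only number a gene model or clone, pseudogene symbols and date symbols were left out of the sets of 12. *Cenpp*, *Lypd2* and similar genes with wild-type values near 0 are low, and their estimates depend on the pseudocount. Members of the marker lists with too few tested genes were named after their values were seen.

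The script for the tests was tested on simulated data for 2 against 2 samples and 12485 genes, with 200 genes changed. Of 50 genes changed by 1 on the log2 scale it called 0%, of 50 changed by 2 it called 6%, of 50 changed by 4 it called 90%, and of 50 changed by 8 it called 98%. It also called 5 unchanged genes. With 200 genes changed, the adjusted threshold is easier to pass than where few genes change, so these shares do not describe the data. A list of 25 genes shifted by 1 gave a camera p of 9.8e-10 and an unshifted list 0.471. The simulated genes varied independently, so this does not show how often camera calls a list whose genes vary together. Alternatives were other pseudocounts (0.1 and 5), no filter or a filter at FPKM 5, median-of-ratios and quantile scaling, the record set term, the replicate number as a block, the first record set only, limma without trend and robust, array weights, leaving out each library, and thresholds of 0.10 or of 0.05 with at least 1 on the log2 scale. For gene lists, members shared between lists were also left out. A further 2 fits, chosen after seeing the data, left out wild-type libraries 1 and 3, or knockout libraries 2 and 3. These fits, and those without wild-type library 2 or knockout library 1, leave 1 sample in a group and 1 residual degree of freedom, so that the lone sample is assumed to vary like the other group. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.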

Results

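Gene expression was measured by RNA sequencing of hearts from adult mice after transverse aortic constriction (TAC), an operation that narrows the aorta and loads the left ventricle with pressure. The animals were operated on at an age of 10 to 12 weeks. Of the 6 libraries, 3 came from wild-type mice and 3 from mice in which *Ltbp4* could be deleted in cardiomyocytes only. The wild-type libraries carry flox in their names, and no label says whether these mice had floxed alleles or a Cre transgene. *Ltbp4* encodes latent transforming growth factor beta binding protein 4, an extracellular protein that binds latent TGF-beta and takes part in elastic fibre assembly. The comparison asked how loss of cardiomyocyte *Ltbp4* altered the pressure-loaded heart, with the NLRP3 inflammasome, a cytosolic complex that activates caspase-1, as the stated interest. No library from an unoperated heart was analysed here, so each difference is between genotypes after TAC and not a response to TAC.

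The recovered depth was low. It came to about 5500000, 3600000 and 5900000 fragments in wild-type libraries 1 to 3, and to about 13900000, 5900000 and 6700000 in knockout libraries 1 to 3. Wild-type libraries 1 and 3 differed by little more than sampling noise, and so did knockout libraries 2 and 3. The variance of their differences was 1.30 to 2.00 times the counting variance at every depth, whereas the other 13 pairs reached 87.1 to 275 times among the deepest genes. Each of these pairs was therefore counted as 1 sample, by its mean, which left 2 wild-type and 2 knockout samples. No label said that the samples came from separate animals, so the limma p-values below rest only on the spread between these samples, moderated over genes. The camera p-values at the preset correlation of 0.01 treat the genes of a list as nearly independent and do not measure that spread. In the 14 lists called, estimated correlations ran from 0.0993 (glycolysis) to 0.955 (cell cycle).

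**Figure D1:**
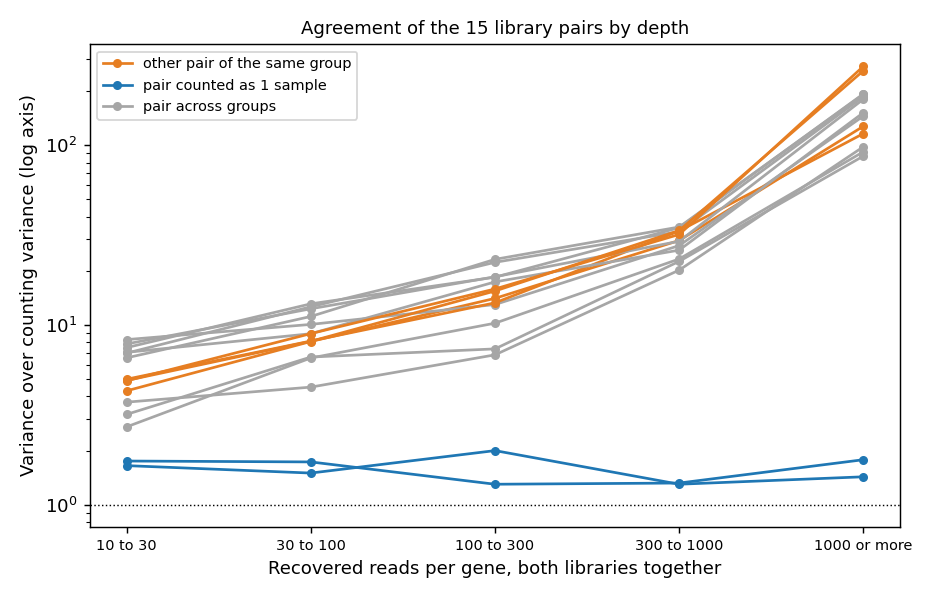
Agreement of the 15 library pairs. The x axis gives recovered reads per gene summed over both libraries, and the y axis (log) the variance of the difference over the variance that counting alone gives. The pairs of wild-type libraries 1 and 3 and of knockout libraries 2 and 3 stayed between 1.30 and 2.00, and the other 13 pairs climbed to between 87.1 and 275.

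After TAC, *Ltbp4* transcript was lower in every knockout library than in every wild-type library, a difference that did not pass. Knockout hearts also carried abundant reads listed under *Esr1*, which was near 0 in wild-type hearts. *Esr1* encodes estrogen receptor alpha, and it was the only gene that passed the test across all genes. Whether its reads come from this gene or from a Cre transgene with estrogen receptor sequence stays open. Transcripts of the fibrillar matrix and fibrosis list, elastic fibres, adipocytes and macrophages were lower in knockout than in wild-type samples as groups, and those of oxidative phosphorylation and the cardiomyocyte sarcomere were higher. Wild-type libraries 1 and 3 carried atrial transcripts and knockout library 1 stood apart, and the fibrillar matrix median went from −1.19 to −0.49 without the former and the sarcomere median from 0.99 to 0.20, no longer called, without the latter. The inflammasome and IL-1 list was also lower as a group, although *Nlrp3* itself was near the limit of detection. These group differences passed a test with a preset correlation between genes and none passed with an estimated correlation.

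The targeted gene *Ltbp4* lies on the minus strand of chromosome 7 (mm10, 27305141 to 27337612) and is annotated as protein coding, with up to 33 exons per transcript. Its FPKM was 368, 248 and 357 in wild-type libraries 1 to 3 and 139, 199 and 195 in knockout libraries 1 to 3. Over samples this was 305 ± 80.9 (SD, n = 2) against 168 ± 41.1 (SD, n = 2), or 45.1% lower. The log2 fold change was −0.86 (SE 0.49, 95% interval −2.03 to 0.32), and it did not pass (limma, Benjamini-Hochberg adjusted p = 0.999). With the 6 libraries as separate samples and a term for the record set, it was −0.87 (limma, Benjamini-Hochberg adjusted p = 0.403). An exact two-sided permutation test of the 6 libraries, 3 against 3, gave p = 0.1, the smallest that it allows, and that of the 4 samples gave p = 0.333, also the smallest possible. The record numbers fall into 2 sets, and the difference was −0.86 within the first and −0.87 within the second, which holds 1 library per genotype. The second set is not independent, since its libraries were counted as repeats of libraries in the first. The value covers *Ltbp4* from all cells of the heart, whereas the deletion concerned cardiomyocytes. Without wild-type libraries 1 and 3, which carried atrial transcripts, the *Ltbp4* estimate was −0.59. The related *Ltbp2* (−2.38) and *Ltbp3* (−1.33) had larger falls and *Ltbp1* (−0.20) a smaller one. An effect of the deletion on this value was thus not separable from a difference in tissue or fibroblast content.

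*Esr1* lies on the plus strand of chromosome 10 (mm10, 4612046 to 5003761) and is annotated as protein coding. It was listed at 0, 0.202 and 0 FPKM in wild-type libraries 1 to 3 and at 1425, 781 and 758 FPKM in knockout libraries 1 to 3. By the recovered depth, this was about 1.8 reads in wild-type library 2 and between 11024 and 47132 reads in the knockout libraries. Values per gene do not show whether these reads come from this locus or from a transgene, so *Esr1* here means the listed value. It rose by 9.90 on the log2(FPKM + 1) scale (SE 0.43; limma, Benjamini-Hochberg adjusted p = 0.0020), a size that depends on the pseudocount because wild-type values lie at the floor. Without a filter on low values the call was lost (limma, Benjamini-Hochberg adjusted p = 0.0514, within a range of 8.24e-05 to 0.0514 over all alternatives). Of 12485 genes tested with limma, 1 rose and 0 fell, and 374 had an unadjusted p under 0.05, where chance gives 624. The 6 libraries as separate samples with the record set term gave the same counts of 1 and 0, with 1438 genes at an unadjusted p under 0.05. Sample values did not overlap between genotypes in 28.3% of genes, and chance gives 33.3% for 2 samples against 2. By library, 1300 of the 12485 genes were higher and 1433 lower in every knockout library than in every wild-type library.

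**Figure D2:**
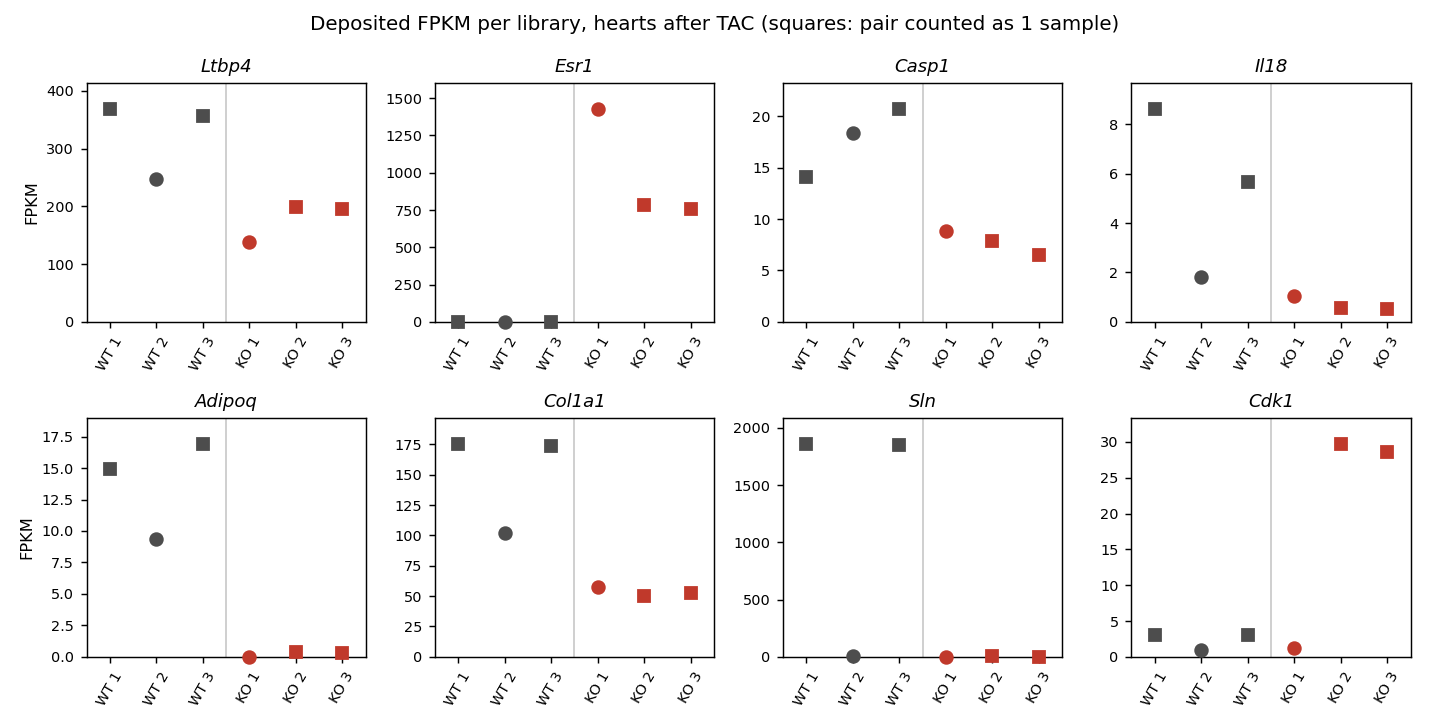
Deposited FPKM (y axes, linear from 0) of 8 genes in the 3 wild-type (WT, grey) and 3 knockout (KO, red) libraries. Squares mark the pairs that were counted as 1 sample. *Ltbp4*, *Casp1*, *Il18*, *Adipoq* and *Col1a1* were lower in all 3 knockout libraries, *Esr1* was near 0 in all 3 wild-type libraries, *Sln* was high in wild-type libraries 1 and 3, and *Cdk1* in knockout libraries 2 and 3.

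The genes with the smallest p in each direction, apart from *Esr1*, did not pass. They were picked by p, so the lack of overlap between their libraries adds no support. Those with higher estimates were *Prelid2*, *Hmgb3*, *Lypd2*, *Eva1a*, *Cenpa*, *Spry4*, *Cenpp*, *Dot1l*, *Naa40*, *Usp28* and *Cish*. Their log2 estimates ran from 1.22 to 2.17, and all 3 knockout libraries lay above all 3 wild-type libraries for each (limma, Benjamini-Hochberg adjusted p = 0.999). Among them, *Cenpa*, which encodes the centromeric histone variant, was at 21.4, 18.4 and 25.8 FPKM in wild type and 48.7, 61.0 and 54.8 in knockout. *Cish*, an inhibitor of cytokine receptor signalling, was at 22.7, 35.9 and 22.4 FPKM in wild type and 85.7, 68.0 and 66.5 in knockout. Those with lower estimates were *Car3*, *Adipoq*, *Cidec*, *Cyp2e1*, *Nnat*, *Hp*, *Fmod*, *Cfd*, *Lgi4*, *Pck1*, *Dio3os* and *Comp*, with log2 estimates from −5.66 to −1.76. All 3 knockout libraries lay below all 3 wild-type libraries for each of these, and the lowest adjusted p was that of *Car3* and *Adipoq* (limma, Benjamini-Hochberg adjusted p = 0.593). *Cfd*, which encodes the adipokine complement factor D, was at 483, 162 and 451 FPKM in wild type and between 0.921 and 15.3 in knockout. *Hp*, which encodes the hemoglobin-binding protein haptoglobin, was at 120, 75.8 and 109 FPKM in wild type and 2.34, 10.2 and 12.6 in knockout.

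In the NLRP3 inflammasome and IL-1 list, 11 of 13 tested members had lower estimates in knockout hearts, with a median log2 fold change of −0.49. *Casp1*, which encodes the protease that matures IL-1 beta and IL-18, was at 14.1, 18.4 and 20.7 FPKM in wild type and 8.84, 7.90 and 6.53 in knockout, a log2 fold change of −1.07 (SE 0.34). *Il18* was at 8.61, 1.82 and 5.65 FPKM in wild type and 1.03, 0.569 and 0.505 in knockout, a log2 fold change of −1.44 (SE 0.59). *Il18bp*, which encodes a secreted inhibitor of IL-18, had an estimate of 0.89 (SE 0.47) in the other direction. *Aim2*, a sensor of cytosolic DNA, had an estimate of −0.63, and *Il1b* of −0.59. By the recovered depth, *Il18* rested on about 23.9, 3.4 and 16.0 reads in wild type and 6.9, 1.7 and 1.7 in knockout. The adaptor gene *Pycard* (−0.46) and the pore-forming *Gsdmd* (−0.61) overlapped between genotypes. No member passed, either across all genes or adjusted over the list alone (limma, Benjamini-Hochberg adjusted p = 0.999 across all genes for *Casp1* and *Il18*). *Nlrp3* was below the filter and was not tested. It was listed at 0.191, 0.218 and 0.457 FPKM in wild-type libraries 1 to 3, from 4, 3 and 10 reads, and at 0.134, 0.135 and 0 FPKM in knockout libraries 1 to 3, from 7, 3 and 0 reads at unequal depth. The list was lower by camera (Benjamini-Hochberg adjusted p = 0.0021), and not with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.612). It was no longer called without wild-type libraries 1 and 3 (median −0.27), which also carried atrial transcripts, nor without knockout libraries 2 and 3 (median −0.33). Macrophage and monocyte markers had lower estimates in the same samples by a larger median (−0.87, 17 of 19 members), and a change within a cell type was not separable from a change in cell numbers.

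Fibrillar matrix genes had lower estimates in knockout hearts in 25 of 28 tested members, with a median log2 fold change of −1.19, and 16 of them were lower in all 3 knockout libraries. *Col1a1* was at 175, 102 and 173 FPKM in wild type and 57.1, 49.9 and 52.7 in knockout, a log2 fold change of −1.28 (SE 0.44). *Col3a1* (−1.29, SE 0.51) and *Postn* (−1.10, SE 0.55), which encodes the matricellular protein periostin, were also lower in every knockout library. The collagen-binding proteoglycan gene *Fmod* (−3.16, SE 0.56), *Comp* (−3.63, SE 0.75) and the lysyl oxidase-like gene *Loxl3* (−2.19, SE 0.51) had the smallest p. These 3 genes passed when adjusted over the list alone and 0 passed across all genes. *Timp1*, a metalloproteinase inhibitor gene, had an estimate of −1.85 (SE 0.54). All 13 tested elastic fibre and microfibril genes had lower estimates, with a median of −1.11. They included elastin (*Eln*, −1.65, SE 0.60), *Efemp1* (−1.70), *Mfap4* (−1.72) and *Loxl1* (−1.11), and 0 passed adjusted over the list alone or across all genes. Both lists were lower by camera (Benjamini-Hochberg adjusted p = 1.58e-15 and 9.41e-09), and neither with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.612 for both). Their medians were −0.49 and −0.58 without wild-type libraries 1 and 3, which carried atrial transcripts. Fibroblast markers also had lower estimates (9 of 10 members, median −0.89). In knockout library 1 the lists parted, with mean deviations of 0.424 for fibroblast markers, −0.491 for fibrillar matrix and −0.38 for elastic fibre genes. In wild-type library 2 they were −0.085, 0.026 and −0.008. Knockout libraries 2 and 3 were low in all 3 lists (−1.117, −0.712 and −0.671). The parting rests on 1 library, so over the samples a change in matrix genes was not separable from a change in fibroblast content.

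In the TGF-beta list, which also holds the other latent TGF-beta binding proteins, 19 of 26 tested members had lower estimates and the median was −0.21. *Ltbp2* was at 112, 43.5 and 109 FPKM in wild type and 12.7 ± 3.23 (SD, n = 2 samples) in knockout, a log2 fold change of −2.38 (SE 0.52). *Ltbp3* was at 77.3 ± 20.3 FPKM in wild type and 29.6 ± 0.540 in knockout (−1.33, SE 0.39), while *Ltbp1* overlapped (−0.20, SE 0.42). The ligand gene *Tgfb3* had an estimate of −0.70 (SE 0.37), *Tgfb2* of −0.34 and *Tgfb1* of 0.48. *Tgfb1* stood at 108 and 101 FPKM in knockout libraries 2 and 3 and at 35.8 in knockout library 1, beside 42.4, 47.0 and 39.1 in wild type. *Nox4*, an NADPH oxidase gene, had an estimate of −2.06 (SE 0.93). None passed across all genes or adjusted over the list alone. The list was lower by camera (Benjamini-Hochberg adjusted p = 0.0040), and not with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.666). It was not called without wild-type libraries 1 and 3 (median 0.06) or without knockout library 1 (median −0.32), and its median was −0.68 without wild-type library 2.

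Markers of several other cell types differed between the samples. All 5 tested adipocyte markers were lower in both knockout samples, with a median log2 fold change of −3.52. *Adipoq*, the adiponectin gene, was at 14.9, 9.34 and 16.9 FPKM in wild type and 0, 0.352 and 0.312 in knockout (−3.52, SE 0.45). *Cidec*, a lipid droplet gene, was at 20.7, 9.52 and 22.1 FPKM in wild type and 0.102, 0.355 and 1.15 in knockout, and *Retn*, the resistin gene, had an estimate of −3.92. All 5 passed adjusted over the list alone and 0 across all genes. Macrophage and monocyte markers had lower estimates in 17 of 19 members (median −0.87), among them *Lgals3* (−1.71, SE 0.59), *Cd163* (−1.60, SE 0.60), *Mrc1* (−1.26) and *Cd14* (−1.11). Fibroblast markers had lower estimates in 9 of 10 members (median −0.89), among them *Dpt* (−1.10, SE 0.49), *Tcf21* (−1.15), *Lum* (−1.19) and *Pi16* (−0.95). Of the macrophage and the fibroblast markers, 0 passed by either adjustment. The adipocyte, macrophage and fibroblast lists were lower by camera (Benjamini-Hochberg adjusted p = 5.79e-14, 1.12e-08 and 0.0022). With an estimated correlation they were not (camera, Benjamini-Hochberg adjusted p = 0.612, 0.612 and 0.666). Without wild-type libraries 1 and 3 the macrophage median was −0.49 and the fibroblast list was no longer called (median −0.31), and without knockout libraries 2 and 3 the fibroblast median was −0.14. The fibroblast median was −1.51 without knockout library 1 and −1.36 without wild-type library 2. The macrophage median was −1.32 without wild-type library 2.

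Atrial cardiomyocyte genes marked wild-type libraries 1 and 3. *Sln*, the atrial calcium pump regulator sarcolipin, was at 1857 and 1847 FPKM there and at 4.31, 0.684, 5.44 and 2.42 in wild-type library 2 and knockout libraries 1 to 3. The atrial light chain gene *Myl4* was at 2629 and 2560 FPKM there and between 8.11 and 16.0 in the other 4 libraries. *Nppa*, the atrial natriuretic peptide gene, was at 30529 and 30706 FPKM there, at 1511 in wild-type library 2, and at 13882, 233 and 232 in knockout libraries 1 to 3. *Dkk3* (−2.35, SE 0.84) and *Stard10* (−1.82, SE 0.81) were lower in all 3 knockout libraries. All 5 tested markers had lower estimates, the list median was −4.10, and 0 passed across all genes or adjusted over the list alone. The list was lower by camera (Benjamini-Hochberg adjusted p = 2.33e-05), and not with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.612). Its median was −0.57 without wild-type libraries 1 and 3 and −7.73 without wild-type library 2.

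Nuclear genes of oxidative phosphorylation had higher estimates in knockout hearts in 49 of 49 members, with a median log2 fold change of 0.96. The complex I genes *Ndufb9* (1.39, SE 0.63), *Ndufa4* (1.42, SE 0.72) and *Ndufs4* (1.14, SE 0.59) and the complex IV gene *Cox5a* (1.54, SE 0.74) had the smallest p. *Cox5a* was between 380 and 415 FPKM in wild type and 2270, 567 and 582 in knockout, so that knockout library 1 stood apart. Genes of the adult sarcomere and of calcium handling had higher estimates in 23 of 23 members (median 0.99). They included *Myl3* (2.41, SE 1.02), *Ldb3* (1.64, SE 0.70) and *Myl2* (2.23, SE 1.12), with *Myh6* at 0.72 and *Atp2a2* at 0.85. *Myl2*, the ventricular light chain gene, was at 1337 and 1337 FPKM in wild-type libraries 1 and 3, at 10403 in wild-type library 2, and at 30483, 10104 and 9968 in knockout libraries 1 to 3. Glycolysis genes had higher estimates in 21 of 22 members (median 0.72), among them *Hk2* (1.56, SE 0.58), *Hk1* (0.76), *Ldha* (0.86) and *Tpi1* (0.86).

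Fatty acid oxidation genes had higher estimates in 25 of 34 members (median 0.56), led by *Ppargc1a* (1.40, SE 0.58), *Ppara* (1.15, SE 0.49) and *Acads* (1.13, SE 0.53). By mean deviation, knockout libraries 2 and 3 lay below wild-type library 2 in oxidative phosphorylation (−0.243 against −0.185) and sarcomere genes (−0.214 against 0.086). Fatty acid oxidation genes did so too (−0.449 against 0.027), and glycolysis genes did not (−0.006 against −0.074). Knockout library 1, the deepest and the only one with a female pattern, stood at 1.23, 1.33, 0.849 and 0.726 in the same order. Of the oxidative phosphorylation, sarcomere, glycolysis and fatty acid oxidation genes, 0 passed across all genes or adjusted over the list alone. The 4 lists were higher by camera (Benjamini-Hochberg adjusted p = 1.29e-15, 1.92e-08, 1.38e-06 and 0.0087, in that order). With an estimated correlation they were not (camera, Benjamini-Hochberg adjusted p = 0.666, 0.666, 0.612 and 0.75). Without knockout library 1 the medians were 0.31, 0.20, 0.35 and −0.26, and the sarcomere and fatty acid lists were no longer called. Without wild-type libraries 1 and 3 they were 0.66, 0.66, 0.49 and 0.36, and the same 2 lists were not called. The sarcomere median was 1.77 without wild-type library 2. The 6 libraries as separate samples with the record set term gave 4 lists higher and 8 lower by camera, against 5 and 9, and did not call the fatty acid oxidation list (median 0.30) or the interferon list.

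Cell cycle genes were higher in knockout libraries 2 and 3 and not in knockout library 1. *Cdk1*, the mitotic kinase gene, was at 29.7 and 28.6 FPKM in these libraries, at 1.26 in knockout library 1, and at 2.98, 0.949 and 3.06 in wild-type libraries 1 to 3. The replication helicase gene *Mcm3* was at 30.7 and 29.9 FPKM there and between 4.26 and 5.74 in the other 4 libraries, and *Mcm2* and *Ccnb1* showed the same order. Estimates were higher in 19 of 20 members, with a median of 1.10, and 0 passed across all genes or adjusted over the list alone. The list was higher by camera (Benjamini-Hochberg adjusted p = 0.0002), and not with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.666). Without knockout libraries 2 and 3 its median was −0.54, and camera called it in the other direction, with the lone knockout sample assumed to vary like the wild-type samples. Without knockout library 1 its median was 2.75.

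**Figure D3:**
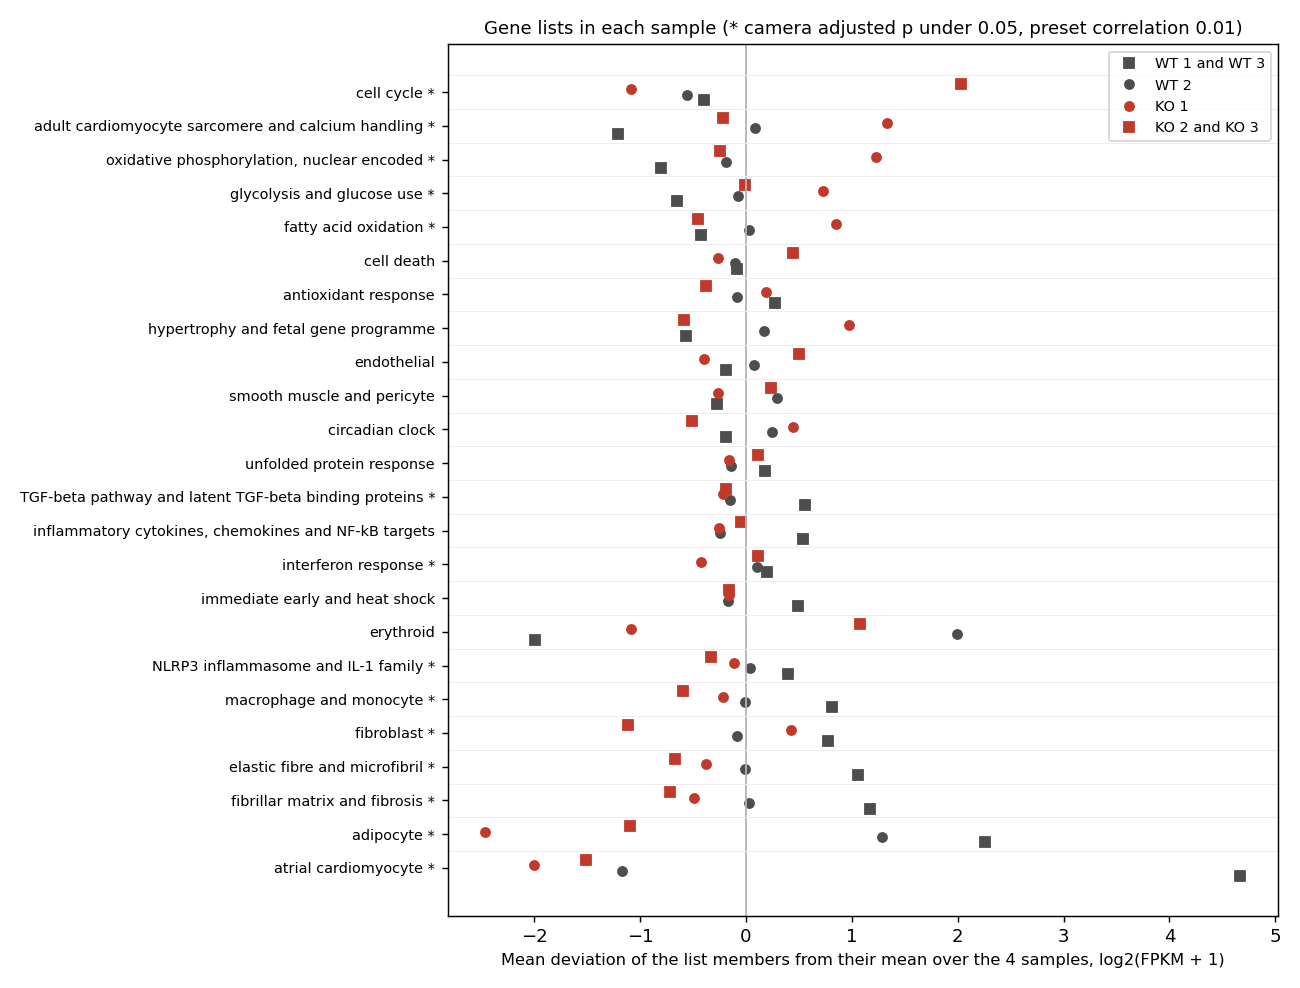
Mean deviation of each gene list in each of the 4 samples from the mean over the samples, on the log2(FPKM + 1) scale (x axis), for the 24 tested lists (y axis, ordered by median log2 fold change). Grey marks wild type (WT), red knockout (KO), and squares the pairs counted as 1 sample. Atrial genes stood at 4.67 in the mean of wild-type libraries 1 and 3, and cell cycle genes at 2.03 in the mean of knockout libraries 2 and 3.

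Interferon response genes had lower estimates in 18 of 23 members, with a median of −0.24. *Zbp1*, a nucleic acid sensor gene, had an estimate of −1.34 (SE 0.43), *Ifi27l2a* of −1.31 (SE 0.56), *Ifit3* of −0.77 and *Xaf1* of −0.45, and 0 members passed by either adjustment. The list was lower by camera (Benjamini-Hochberg adjusted p = 0.0077), and not with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.666). It was not called in the 6 libraries as separate samples (median −0.15), without knockout library 1 (median 0.06) or without wild-type libraries 1 and 3 (median −0.30). With neither knockout library 2 nor 3 the median was −0.51. The mean deviation of the list was −0.425 in knockout library 1 and 0.119 in the mean of knockout libraries 2 and 3, so the fall rested on knockout library 1.

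Genes of hypertrophy and of the fetal programme, which rise under pressure load, did not differ as a list (camera, Benjamini-Hochberg adjusted p = 0.124; median 0.09), but this rested on single libraries. The median was 0.97 without wild-type library 2 and 1.12 without knockout libraries 2 and 3, and −0.07 without knockout library 1. Camera called the list higher in the first 2 of these fits, in which the lone sample is assumed to vary like the other group. *Xirp1* (1.53, SE 0.58) and *Rcan1* (0.75, SE 0.42), a calcineurin target, were higher in all 3 knockout libraries, while *Csrp3*, *Nppa*, *Nppb*, *Acta1* and *Myh7* overlapped. *Nppb*, the B-type natriuretic peptide gene, was at 640, 250 and 605 FPKM in wild type and 1046, 122 and 134 in knockout (−0.11, SE 1.02). *Myh7*, the fetal myosin heavy chain gene, was at 4.89, 228 and 5.71 FPKM in wild type and 782, 47.1 and 45.4 in knockout (2.34, SE 1.86). The lists of immediate early genes (camera, Benjamini-Hochberg adjusted p = 0.0501) and of cytokines and chemokines (camera, Benjamini-Hochberg adjusted p = 0.0772) were not called. The former was close to the threshold and was called lower in 8 of 20 alternative fits, among them both pseudocounts and both scalings, and the latter in 2 of 20. Their medians were −0.62 and −0.80 without wild-type library 2, and 0.02 and 0.11 without wild-type libraries 1 and 3. Among the members of these lists, *Fos* (−2.10, SE 0.79), *Fosb* (−1.67), *Junb* (−0.89), *Ccl6* (−1.28, SE 0.56) and *Ccl9* (−1.12) were lower in all 3 knockout libraries. Members went both ways, with higher estimates in 8 of 22 immediate early genes and 11 of 27 cytokine and chemokine genes. In all 3 knockout libraries, 4 immediate early genes were lower and 2 higher, and 3 cytokine and chemokine genes were lower and 3 higher. The lists of cell death, endothelial, antioxidant, erythroid, unfolded protein response, circadian and smooth muscle genes were not called either (camera, Benjamini-Hochberg adjusted p = 0.289 to 0.91). Without knockout library 1, the cell death (median 0.53) and endothelial (median 0.47) lists were called higher and the circadian list (median −0.37) lower, in a fit with a lone knockout sample. Among their members, the endothelial receptor gene *Kdr* had an estimate of 1.16 (SE 0.47), *Mt2* of −1.74 (SE 0.59), *Gpx3* of −1.83 and *Sod3* of −1.55. For the antioxidant list the median (0.16) and the mean (−0.19) differed in sign, and so did those of the smooth muscle list (0.02 and −0.02).

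The sex-linked transcripts were not balanced between the groups. *Xist*, which is expressed from the inactive X chromosome of females, was at 41.9 FPKM in knockout library 1 and at or below 0.061 in the other 5 libraries. The Y-linked genes *Ddx3y*, *Uty*, *Kdm5d* and *Eif2s3y* were listed at 0 in knockout library 1 and were present in the other 5, with *Eif2s3y* between 35.1 and 54.0 FPKM. Knockout library 1 was thus the only library with a female pattern, and sex differs between the 2 knockout samples.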

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

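The tests that left out a pair of libraries were chosen after the results were seen. *Ltbp4* kept its direction and stayed short of the threshold under every alternative, with log2 fold changes from −1.13 to −0.59 (−1.13 to −0.61 when leaving out 1 library). The gene counts were 0 higher without a filter on low values, which raised the number of genes tested to 16954, and 1 lower (*Adipoq*) for 6 libraries with no record set term. When leaving out 1 library, 1 to 2 genes were higher and 0 to 10 lower. The upper ends, without wild-type library 2, rest on the lone sample of wild-type libraries 1 and 3, which is assumed to vary like the knockout samples, and included *Myl4*, *Sln*, *Cyp2e1* and *Car3*. With neither knockout library 2 nor 3, 2 genes were higher and 3 lower. The *Esr1* estimate was higher in every fit, and only the fit without a filter did not call it. Among the lists, 0 higher and 0 lower were called with an estimated correlation (lowest adjusted p = 0.612) and 0 and 0 with fry (lowest adjusted p = 0.866), against 5 and 9. When leaving out 1 library, 5 to 7 lists were higher and 8 to 11 lower, the most without wild-type library 2. Of the 10 lists not called, 7 were called in some fit: immediate early in 8 of 20 fits, erythroid in 3, cytokines, hypertrophy, circadian and endothelial in 2 each, and cell death in 1. With neither wild-type library 1 nor 3, 3 lists were higher and 6 lower, and the planned fit of 6 libraries with the record set term gave 4 and 8. The sign of the median changed in 28 of 479 list values, over 14 lists, among them TGF-beta (0.06, with neither wild-type library 1 nor 3), and cytokines (0.17), interferon (0.06) and antioxidant genes (−0.15) without knockout library 1, and cell death (−0.27) and endothelial genes (−0.37) with neither knockout library 2 nor 3. The camera direction changed, for a list called in either fit, for erythroid 0.77 without wild-type library 2 (−0.43 without knockout library 2), fatty acid oxidation −0.26 (0.76 without wild-type library 2) without knockout library 1, and cell cycle −0.54, circadian 0.45 and fibroblast −0.14 (whose median kept its sign) with neither knockout library 2 nor 3. The cause was not tested beyond the per-sample values. Correlations of deviations between same-numbered libraries were 0.12, 0.12 and −0.10. Every wild-type and knockout library gave a value between −0.13 and 0.12, since each group holds 1 close pair, so pairing by number could not be judged. A block for the replicate number gave 1 gene higher and 0 lower, −0.87 for *Ltbp4*, and 4 lists higher and 9 lower. With the first record set only, 1 and 0 genes and 5 and 9 lists were called. This set holds the same 4 samples with the repeat libraries left out. Leaving out 1 library of a close pair removes no sample either, so all these fits had to stay near the reported one. Over all named genes and alternatives, 2585 estimates kept both their sign and their call or lack of one, whatever their size. A further 44 moved across 0 without a call, 9 gained a call and 1 lost it. Only *Esr1* was called in the reported fit, so the other genes had no call to lose. Depth limits low genes such as *Nlrp3*. In the simulation, 2 samples per group called 6% of the changes of 2 and 90% of those of 4 on the log2 scale, and no size between was tried. These shares do not carry over to the data, where *Cfd* (−5.66) and *Cyp2e1* (−4.46) were not called.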

Other observations

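All tests in this part were chosen after the results were seen. Several marker lists were too short to test, and their values describe the samples. Neutrophil genes were low in all libraries and highest in knockout library 1, where *S100a8* was at 41.3 FPKM and *S100a9* at 28.2, against at most 19.6 and 7.83 elsewhere. T cell genes were near the floor, with *Cd3e* at or below 0.621 FPKM in every library. Of the B cell genes, *Cd79b* was at 6.85, 2.93 and 6.59 FPKM in wild type and 1.53, 0.365 and 1.62 in knockout. The mesothelial gene *Msln* was at 13.7, 11.2 and 16.0 FPKM in wild type and 4.98, 3.95 and 5.61 in knockout, whereas *Wt1*, which marks the epicardium, was highest in knockout libraries 2 and 3 (18.9 and 16.4 FPKM). The fast skeletal muscle genes *Myh1*, *Myh2* and *Myh4* were at or below 0.095 FPKM throughout, and *Tnnt3* was at 22.3 FPKM or more in wild-type libraries 1 and 3 and between 2.16 and 3.37 elsewhere.

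Some blood and clock transcripts differed between samples of 1 genotype. The globin gene *Hbb-b1* was at 2036 FPKM in wild-type library 2 and at 1262 and 1196 in knockout libraries 2 and 3, against 370 to 411 in the other 3 libraries. The globin genes *Hba-a1* and *Hba-a2* have near-identical sequences, and *Hba-a2* went from 0.0635 to 1299 FPKM, so that their split is uncertain. The circadian list was not called, and its genes showed several orders, of which *Dbp* is 1 example, at 196 FPKM in wild-type library 2, 152 in knockout library 1, at most 62.2 in wild-type libraries 1 and 3, and 22.7 and 20.1 in knockout libraries 2 and 3. In the 6 libraries, the first principal component held 52.0% of the variance and set wild-type libraries 1 and 3 against knockout libraries 2 and 3, and the second (30.5%) set knockout library 1 apart.

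The first pattern is the near identity of 2 pairs of libraries with different titles. Processing that made all libraries alike is argued against, since the lowest index of the other pairs among the deepest genes was 87.05. The 2 close pairs reached at most 1.78 there, and the other same-group pairs at least 116.13, so the close pairs differed far less. This is no separate test of whether they come from separate animals, since a low index picked them. The other same-group pairs also differ in atrial transcripts or in sex, and do not show how similar animals vary. Whether each pair comes from 1 library or 1 RNA preparation stays open, because the index of at most 2.00 in any depth bin is what picked the pairs and so is no test of it.

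The second pattern is *Esr1* at 758 FPKM or more in knockout libraries. The female sex of knockout library 1 is argued against, since knockout libraries with Y-linked transcripts had at least 757.9 FPKM. A change of the whole region is argued against by a median log2 fold change of 0.29 over the 12 tested genes within 2 Mb. An inducible Cre transgene that carries estrogen receptor sequence, as tamoxifen-dependent Cre does, is a candidate source, and the labels do not name the Cre line. The ratio of *Esr1* to *Myh6* differed 1.23-fold between the knockout samples and *Esr1* itself 1.85-fold. However, 2 samples and values per gene cannot settle whether the reads come from the transgene, so it stays open. If they do, the wild-type libraries lacked this transgene by their *Esr1* values. Its effect would then not be separable from that of *Ltbp4* loss.

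The third pattern is the lower level of adipocyte and matrix transcripts in knockout hearts. Atrial and adjoining tissue in wild-type libraries 1 and 3, whose *Sln* and *Myl4* values mark them, is argued against as the only cause for adipocyte genes, since their median was −3.16 without these libraries, with wild-type library 2 assumed to vary like the knockout samples. For the fibrillar matrix list, the median went from −1.19 to −0.49 without them, which leaves 1 wild-type library to compare, so that tissue and genotype cannot be told apart. The bound of 0.25 for no remaining difference was set after this value was seen. By the first bound of 0.5, the median of −0.49 would have counted as no remaining difference and tissue as a sufficient cause. A comparison with 1 wild-type library cannot show that. The female sex of knockout library 1 is argued against for the matrix list, whose median was −1.43 without it on the same kind of assumption, while how much fat was dissected with each heart is not given in the labels, and a true effect of the genotype stays open as well, as untested.

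The 4 samples allow only 3 splits into 2 against 2, too few for a share under 0.05. The real split called 1 gene, as 1 of the 3 splits did, and the highest count of the others was 0. It had the fewest genes at an unadjusted p under 0.05, with 374 against 431 and 1139. It called 14 gene lists, and 2 of the 3 splits called as many, the highest other count being 16, for wild-type libraries 1 and 3 with knockout libraries 2 and 3 against the rest. That split calls lists from the structure of the samples, which makes the list calls at the preset correlation weak evidence of a genotype effect.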
